A study of Homo sapiens with 6 samples.

How the data were processed

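RNA was measured in small extracellular vesicles released by spheroids of Cal27, an established line of tongue squamous carcinoma cells. The spheroids were held for 14 days in Matrigel, a gel of basement membrane proteins, at 3 mg/mL for the soft condition and 12 mg/mL for the stiff one, per the labels. Vesicles were collected from the medium by insulator-based dielectrophoresis, which traps particles in an electric field shaped by insulating structures. Total RNA was purified with a miRNeasy Micro kit, and about 10 ng was made into libraries with the NEBNext Ultra II Directional RNA kit and 9 PCR cycles, per the labels. The libraries were read in pairs of 61 bp on an Illumina NextSeq instrument, with about 44M reads, per the labels. A DNase step, a poly(A) selection and a removal of ribosomal RNA were not given in the sources used here. There were 6 libraries in 2 groups of 3, which the labels name biological replicates. In the labels' descriptions 2 stiff libraries carried the same replicate number, and the numbers in the titles were used.

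The deposited values were raw counts of reads per gene symbol for 38167 genes in 1 table, with no normalization by the authors. Reads were trimmed with Trim Galore 0.4.2 and cutadapt 1.9.1, checked with FastQC 0.11.7, aligned with STAR 2.6.1e to hg38 and counted with featureCounts 1.6.2, per the submitters' processing notes, which also name DESeq2 1.26.0. These roles are the usual ones of those tools, since the notes list names without roles. The gene annotation, the strand setting, the handling of reads that fit several places and the handling of reads that overlap several genes were not given in the sources used here. The counts themselves bear on the last point. In every copy of the 45S ribosomal RNA gene the count nearly equalled the sum of the counts of the 18S, 5.8S and 28S genes inside it in the stiff libraries, which is what counting a read for each gene it overlaps gives. Shares of counts taken by ribosomal RNA therefore overstate shares of reads. Genes with near-identical copies, such as the 45S and 7SL genes, and genes with many processed copies, such as EEF1A1, GAPDH and TPT1, are uncertain one by one.

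Totals ranged from 2445498 to 2977837 counts per library. Replicates of a group differed by more than sampling noise in every pair. The chi-square per degree of freedom was 1.47 to 1.60 over 31016 to 31037 genes. PCR also adds such noise, so this check cannot tell biological from technical replicates. Each library was counted as 1 sample because the labels name them biological replicates. PCR reads without molecular identifiers are not independent molecules.

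Gene symbols were matched to a RefSeq gene table, which held 35945 (94.2%) of them, and 27332 (71.6%) had a gene in GENCODE release 29, whose transcripts gave exon lengths and GC content. Coordinates are those of GRCh38. Stiff was compared with soft by edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr, robust quasi-likelihood fits and two-sided F tests, with group as the single term. The filter removed 7093 genes and left 31074. Benjamini-Hochberg adjustment ran over all genes tested, and an adjusted p under 0.05 counted as a call. Adjusted p-values below come from this fit unless another tool is named. Standard errors were derived from the F statistic. CPM values were scaled by TMM.

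The procedure was tested on simulated counts drawn from the means and library sizes of this comparison for 30605 genes. It recovered 37.3% of genes planted at 1.5-fold, 82.8% at 2-fold and 100% at 4-fold, and 4.03% of its calls were unchanged genes. Of 20 simulated unchanged lists 0 were called, and a planted list of 30 genes at 1.2-fold reached adjusted p = 1.82e-08. Simulated genes were drawn independently, with a single dispersion of 0.007 and no trend with GC content. These rates therefore do not cover correlated genes or GC bias in the real libraries.

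The design, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. Chosen later were the class of ribosomal RNA genes, the correction for GC content, the counts per kb of exon, the 45S counts outside the mature parts and the chromosome levels. There were 24 lists, holding 805 genes of which 3 were not found, with camera (limma 3.58.1, preset correlation 0.01) as the set test and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it, and fry also, chosen later, on random lists of the same sizes. The lists covered mechanosensitive channels, YAP/TAZ targets, integrins and focal adhesion, matrix and its remodelling, the basement membrane proteins of Matrigel, epithelial-mesenchymal transition, epithelial junctions, basal keratinocytes, keratinocyte differentiation, hypoxia, the cell cycle, vesicle biogenesis and markers, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, replication-dependent histones, small structured non-coding RNAs, nuclear-retained long RNAs, the interferon response, and the unfolded protein and integrated stress response. A further 3 held markers of cells or material that a Cal27 culture should not make, namely haematopoietic and erythroid cells, stroma and endothelium, and serum and liver. The result of 1 list and of 1 gene is not reported here.

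Named genes were PIEZO1, the 10 genes with the largest fold change in each direction among calls with a mean of at least 5 CPM and groups that did not overlap, up to 4 called members of each list (or, with none called, the member with the smallest p and the most abundant one), and the 10 most abundant genes. Genes outside this rule are marked where they appear, except the members given as higher or lower adjusted over their list alone, which were all named after their values were seen. Shares of counts, totals and genes with at least 10 counts were compared by two-sided exact permutation tests over the libraries, where 3 against 3 cannot give a p below 0.1. Counts per kb used genes with at least 200 bp of exon. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.

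Alternatives were other scaling factors (RLE, upper quartile, library totals alone), DESeq2 1.42.0 with and, chosen later, without its independent filtering, limma-voom, fits without robust estimation, no filter, a filter of 5 CPM in 3 libraries, leaving the mitochondrial, ribosomal and small structured RNAs out, the replicate number as a block, each library left out in turn, an adjusted p under 0.1, a test against a 1.5-fold change, other denominators and detection limits, and the GC correction. The GC correction (a lowess curve per library, span 0.3) could be run on 23239 genes, since 74.5% of the genes tested had a GC value, and on 99.3% of the nuclear protein-coding ones.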

Results

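The series asked how the stiffness of the surrounding matrix alters the vesicles that squamous carcinoma spheroids release, with Piezo1, a stretch-gated cation channel, named in its title as a cargo. The data were gene counts of vesicle RNA from 3 libraries of spheroids in soft Matrigel and 3 of spheroids in stiff Matrigel. Soft libraries held 2445498, 2525947 and 2545385 counts and stiff libraries 2697502, 2900205 and 2977837. At least 1 count was seen for 97.5% to 97.9% of the 38167 genes in every library. Genes with at least 10 counts numbered 31206 ± 188 (SD, n = 3) in soft and 30725 ± 250 (n = 3) in stiff, a difference at the smallest p that 3 against 3 libraries allow (exact permutation p = 0.1).

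Vesicle libraries from stiff Matrigel held far fewer counts of mitochondrially encoded genes and far more of ribosomal RNA than those from soft Matrigel. The 13 mitochondrial messenger genes, which encode subunits of the respiratory chain and ATP synthase, took 1.63% ± 0.170 of counts in soft and 0.176% ± 0.0219 in stiff libraries (SD, n = 3 each), which is 9.23-fold less in stiff. Ribosomal RNA genes took 5.35% ± 3.11 in soft and 21.6% ± 1.44 in stiff, a 4.03-fold higher share. Soft replicate 3 had the highest share of its group at 8.87%, against 2.97% and 4.20% in the other soft libraries, and without it the ratio was 6.02. Small structured non-coding RNAs, among them the 7SL RNA of the signal recognition particle, took 0.0350% ± 0.0204 and 0.0908% ± 0.00379, which is 2.59-fold higher in stiff. Histone genes of the replication-dependent kind, whose messengers end in a stem-loop and not in a poly(A) tail, took 0.0416% ± 0.00522 in soft and 0.0286% ± 0.000287 in stiff. Each of these 4 classes had groups that did not overlap, and each reached the smallest possible p (exact permutation p = 0.1). Cytosolic ribosomal protein genes took 0.108% ± 0.00401 and 0.104% ± 0.00365 of counts, and these groups overlapped (exact permutation p = 0.2). As a share of protein-coding counts alone, their ratio of stiff to soft was 1.15 where it was 0.958 over all counts.

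**Figure D1:**
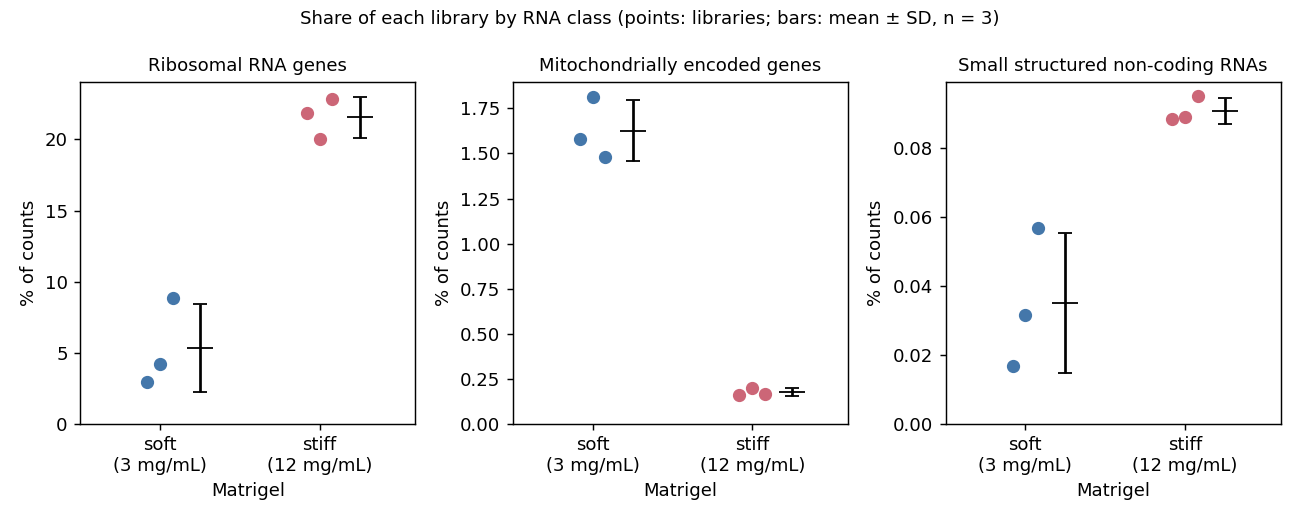
Percent of each library's counts taken by ribosomal RNA genes, mitochondrially encoded genes and small structured non-coding RNAs, with 1 point per library and the mean ± SD of 3 libraries beside them. Stiff libraries lie above soft ones for ribosomal RNA (21.6% against 5.35%) and below them for mitochondrially encoded genes (0.176% against 1.63%).

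Across all genes, 140 of 31074 passed the threshold between stiff and soft, 89 of them higher in stiff and 51 lower. All 13 mitochondrial messenger genes were among the lower ones. Of 12 ribosomal RNA genes tested 6 were higher, and of 9 small structured RNAs 2 were higher. Nuclear protein-coding genes gave 78 higher and 16 lower of 18764 tested, and long non-coding RNAs 2 higher (HAR1A and LINC02714, named after their values were seen) and 17 lower of 9361. The count depended on which libraries were kept. It was 95 without soft replicate 1, 77 without soft replicate 2 and 136 without soft replicate 3. It was 85 without stiff replicate 1, 60 without stiff replicate 2 and 75 without stiff replicate 3. These fits had 2 libraries in the smaller group. Without soft replicate 1, 49 genes were higher in stiff and 46 lower, and without soft replicate 3, 103 were higher and 33 lower. DESeq2 called 67 genes, 47 higher and 20 lower, but its own filter on mean count left an adjusted p for only 2157 genes and none for 74 of the 140. Without that filter it called 43, of which 38 were among the 140. Scaling by library totals alone moved the median log2 fold change of all genes to −0.27 and gave 31 higher and 4163 lower, so fold changes here are relative to the middle of the distribution, which TMM put at −0.00484. Correction for GC content, over the 23239 genes with a GC value, gave 27 higher and 47 lower.

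Ribosomal RNA genes had the largest increases. RNA45SN3, RNA45SN2 and RNA45SN1, copies of the precursor gene on chromosome 21 (8389035 to 8402343, 8205988 to 8219302 and 8433222 to 8446572, GRCh38), rose by 2.20 ± 0.24, 2.16 ± 0.24 and 2.13 ± 0.24 on the log2 scale (± SE, n = 3 per group; adjusted p = 3.74e-13, 2.18e-12 and 1.15e-12). Without a filter on low counts the fold changes stayed at 2.20, 2.17 and 2.13 while the adjusted p-values were 0.360, 0.368 and 0.354, within ranges that began at 5.11e-37, 2.99e-35 and 2.12e-33. RNA5-8SN2, which encodes the small ribosomal RNA between 18S and 28S in the second of these, rose by 1.07 ± 0.11 (adjusted p = 1.42e-14). The 18S and 28S genes inside the same units are among the 10 most abundant genes and had fold changes of 2.26 to 2.45 on the log2 scale without passing the threshold, with adjusted p from 0.0569 for RNA28SN1 to 0.337 for RNA18SN2, while DESeq2 called all 6 of them (adjusted p = 0.00185 to 0.00530), or 5 without its filter on mean count (0.0543 for RNA18SN2), and limma-voom 4. Copies share reads, and the sum over all ribosomal RNA genes was 134850 ± 80521 counts in soft and 616930 ± 55500 in stiff, a ratio of 4.57. Dividing shared reads between copies would leave this sum the same. It appears to count a read in a mature part under each gene that the read overlaps. The 45S genes alone summed to 73143 ± 40500 and 312570 ± 27784, a ratio of 4.27. The ratio over all ribosomal RNA genes was 6.90 without soft replicate 3, the highest of its group, and 3.72 without soft replicate 1. The 45S counts outside these mature RNAs did not follow. They stood at 11460 ± 1317 in soft and 8238 ± 358 in stiff, or 18.5% ± 7.62 and 2.65% ± 0.236 of the 45S counts (exact permutation p = 0.1 for both).

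Among other genes higher in stiff, ANP32B, a histone chaperone, rose by 1.75 ± 0.16 on the log2 scale, from 18.03 ± 7.58 to 60.4 ± 6.78 CPM (SD, n = 3 per group; edgeR adjusted p = 2.70e-19). It lies on chromosome 9 (97983341 to 98015943). Its counts were 36, 39 and 71 in soft and 151, 141 and 174 in stiff libraries, in replicate order. They ranked the libraries as the summed ribosomal RNA counts did (72660, 106093 and 225805 in soft, 589224, 580733 and 680826 in stiff). The rise of ANP32B is therefore not shown to be separate from that of ribosomal RNA. TMSB10 and SLCO5A1 also had their highest soft count in soft replicate 3, and EEF1A1 did not. TMSB10, which encodes an actin-sequestering thymosin and lies on chromosome 2 (84905656 to 84906671), rose from 5.42 to 15.7 CPM (log2 fold change 1.53 ± 0.29, adjusted p = 0.000313). SLCO5A1, a member of the organic anion transporter family on chromosome 8 (69667046 to 69834978), rose from 86.3 to 195 CPM (1.18 ± 0.11, adjusted p = 5.76e-11). EEF1A1, the translation elongation factor that carries aminoacyl-tRNA to the ribosome, rose from 14.4 to 30.1 CPM (1.07 ± 0.19, adjusted p = 0.000115). RN7SL3, a 7SL RNA gene, rose by 1.31 ± 0.26 (adjusted p = 0.000714), and RPPH1, the RNA of ribonuclease P, rose by 0.97 ± 0.21 (adjusted p = 0.00361). RN7SL3 lost its call without stiff replicate 3 (adjusted p = 0.0610, range over alternatives 0.000420 to 0.0610), and RPPH1 without soft replicate 2 (0.0560) or stiff replicate 2 (0.0625), or with DESeq2 (0.0819, range 0.00233 to 0.0819). Of these genes, DESeq2 with its filter gave no adjusted p for ANP32B, TMSB10, EEF1A1, RN7SL3 and RPPH1. Without that filter, DESeq2 called ANP32B (adjusted p = 0.000117), TMSB10 (0.0258), EEF1A1 (0.00657) and RN7SL3 (0.0406). Picked out after their values were seen, TPT1 (0.96), PABPC1 (0.92), GAPDH (0.88) and SET (0.65) also passed the threshold upwards, and like EEF1A1 they kept the call after GC correction, while RPL13 (0.01) and all other ribosomal protein genes did not pass.

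Genes lower in stiff were led by the mitochondrial genome. ND6 fell by 3.03 ± 0.08 on the log2 scale, from 1090 ± 113 to 133 ± 17.5 CPM, an 8.18-fold decrease (SD, n = 3 per group; edgeR adjusted p = 2.16e-96). ATP8 and ATP6, subunits of ATP synthase, had log2 fold changes of −3.03 and −3.02. Those of ND1 and ND2 were −3.02 each, and those of CYTB, ND4L, ND5, COX1 and COX3 were −2.99, −2.93, −2.92, −2.91 and −2.90. The smallest falls, outside the rule for named genes and picked out after their values were seen, were those of ND4, COX2 and ND3, at −2.87, −2.84 and −2.70. ND5 was the most abundant of them, at 2676 ± 222 CPM in soft and 354 ± 43.7 in stiff. All 13 had the same direction and passed in all 18 alternative fits that tested them, and their median lay between −2.85 and −3.20. Outside the mitochondrial genome, GRHL2, a transcription factor of epithelial junction genes on chromosome 8 (101492439 to 101681200), fell by 0.56 ± 0.12, from 68.9 to 46.9 CPM (adjusted p = 0.00418). Its call was lost without stiff replicate 2 (adjusted p = 0.106) and with DESeq2, which gave GRHL2 no adjusted p with its filter and 0.108 without it (log2 fold change −0.55, range of adjusted p over alternatives 2.31e-07 to 0.108).

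**Figure D2:**
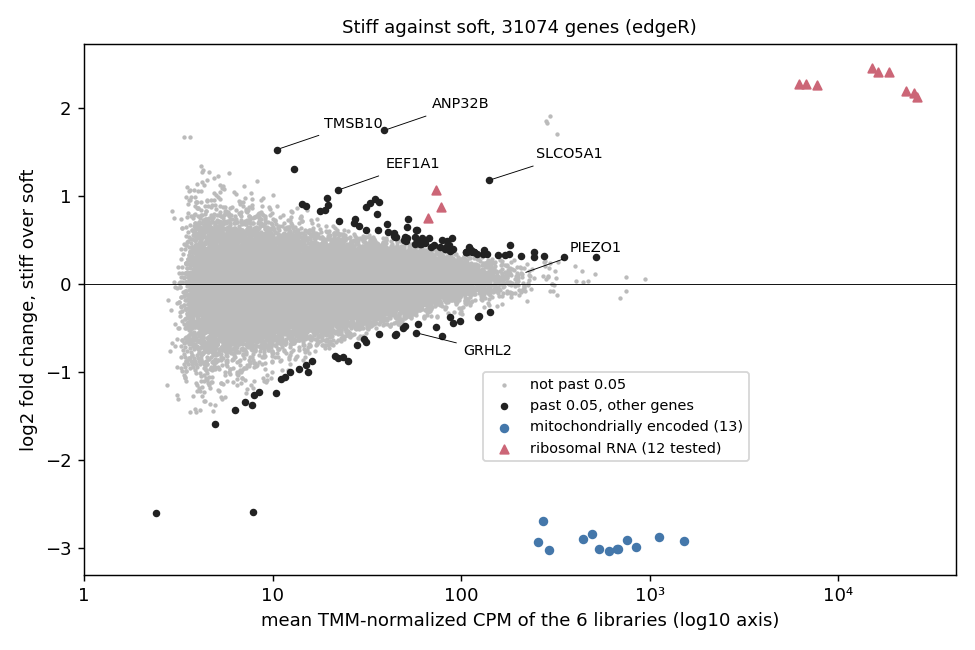
Log2 fold change of stiff over soft against mean CPM of the 6 libraries (log axis) for the 31074 genes tested, with the 13 mitochondrial genes, the 12 ribosomal RNA genes tested and all other genes past the threshold marked. The mitochondrial genes form a separate group near −3, and the 45S, 18S and 28S genes lie at the upper right, with 6 of the 12 ribosomal RNA genes past the threshold.

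PIEZO1 counts did not differ detectably between the conditions. The gene (chromosome 16, 88715338 to 88785220) had 531, 528 and 589 counts in the soft libraries and 507, 573 and 619 in the stiff ones, or 203 ± 16.9 and 220 ± 14.0 CPM (SD, n = 3 each). Its log2 fold change was 0.12 ± 0.075 (SE; edgeR adjusted p = 0.659). Over 19 alternatives it was called in 0, with fold changes from −0.15 under library totals alone to 0.19 and −0.00274 after GC correction. PIEZO1 had 44.9 to 54.8 counts per kb of exon, against a median of 30.9 to 35.4 for 261 protein-coding genes of its chromosome with like GC content, which placed it at percentiles of 80.5 to 86.2 among them. Mechanosensitive channels as a list had 1 of 37 members past the threshold, and 1 adjusted over the list alone (camera adjusted p = 0.499). That member was PKD1, the polycystin-1 gene, which rose by 0.30 ± 0.069 (adjusted p = 0.00935). It has near-identical pseudogene copies, and its call was lost under library totals alone, without robust dispersion, after GC correction (adjusted p = 0.486) and without soft replicate 2 (0.0890), stiff replicate 1 (0.0897) or stiff replicate 2 (0.0652), over a range of 0.000217 to 0.750.

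Of the 24 gene lists, 5 passed the camera test, and with an estimated correlation only the mitochondrially encoded list did (adjusted p = 0.000301 with an estimated correlation). All 13 of its members fell, and the same 13 fell adjusted over the list alone. Cytosolic ribosomal protein genes were higher as a list (camera adjusted p = 0.000224, and adjusted p = 0.0601 with an estimated correlation), with 54 of 72 members above 0 and a median log2 fold change of 0.20. None passed singly over all genes (0 of 72 by edgeR), and 6 were higher adjusted over the list alone, RPLP0 and RPLP1 of the ribosomal stalk among them. An unadjusted edgeR p under 0.05 was seen for 10 of the 72, against 2955 of all 31074 genes. Under library totals alone the list's median was −0.07, above the −0.27 of all genes. RPL13, the member with the most counts, over 6172 bp of exon, had 43.7 and 44.0 CPM. Small structured RNAs were higher as a list (camera adjusted p = 0.00182, and adjusted p = 0.276 with an estimated correlation), with RN7SL3 and RPPH1 called of 9 by edgeR, against 4 by limma-voom and 0 by DESeq2 with its filter, which gave RN7SL3 and RPPH1 no adjusted p. Adjusted over the list alone, 5 were higher, which adds RN7SL1, RN7SL2 and RN7SK, and 1 was lower, RNU1-1, the U1 spliceosomal RNA. With no filter on low counts that list's adjusted p was 0.616, over a range of alternatives that began at 1.2e-32. The 7SL genes summed to 690 ± 518 counts in soft and 2398 ± 225 in stiff, a ratio of 3.47 that was 5.86 without soft replicate 3 and 2.61 without soft replicate 1.

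Replication-dependent histones were lower as a list (camera adjusted p = 0.00241, and adjusted p = 0.276 with an estimated correlation), with a median of −0.29, 7 of 38 members above 0 and 0 called over all genes. H2AC13 and H2BC13 were lower adjusted over the list alone. H2BC13 had 7.09 ± 3.10 CPM in soft and 2.58 ± 0.739 in stiff (adjusted p = 0.0913), and H4C15, the most abundant member, 20.4 and 19.6. Under library totals alone the list lost its call (camera adjusted p = 0.495, over a range of alternatives that began at 0.000392). Its median there was −0.56, still below the −0.27 of all genes.

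Programmes of adhesion and matrix showed single genes and no call as lists by camera. The mixed test of fry counts changes in either direction. It passed for matrix and its remodelling (adjusted p = 0.00197), the basement membrane (0.0107) and YAP/TAZ targets (0.0162). That test is not specific here. Of 240 lists drawn at random from other protein-coding genes, 63 also had an adjusted p under 0.05 in it, and 98 an unadjusted p under 0.05. Integrins and focal adhesion genes had 1 of 38 called (camera adjusted p = 0.439). It was PLEC, which encodes plectin, a linker of keratin filaments to hemidesmosomes, and which rose by 0.30 ± 0.068 (adjusted p = 0.00896). Adjusted over the list alone, PLEC was higher and ITGB8 lower. Matrix and matrix remodelling genes had 1 of 45 called (camera adjusted p = 0.409), COL6A2 of collagen VI, which rose by 0.39 ± 0.085 (adjusted p = 0.00586). Adjusted over the list alone, 3 were higher, COL6A2, COL6A1 and LAMA5. Calls of PLEC and COL6A2 were lost under library totals alone, after GC correction (adjusted p = 0.465 and 0.275) and without soft replicate 2 (0.103 and 0.0830) or stiff replicate 2 (0.128 and 0.0988), that of PLEC also without soft replicate 1 (0.0575) and without robust dispersion, and that of COL6A2 also with DESeq2 without its filter (0.0819, against 0.00805 with it), over ranges of 1.08e-05 to 0.761 and 0.00248 to 0.357. Basement membrane genes, whose proteins make up Matrigel, had 0 of 9 called and 1 higher adjusted over the list alone, AGRN (172 and 208 CPM, adjusted p = 0.0721), with HSPG2 at 226 and 240 CPM (list adjusted p = 0.311). YAP/TAZ targets had 0 of 34 called and 1 higher adjusted over the list alone, NT5E (25.4 and 36.8 CPM, adjusted p = 0.118), while ARHGEF17 stood at 128 CPM in both (list adjusted p = 0.384).

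Epithelial identity genes gave 2 calls in opposite lists. Among epithelial junction genes GRHL2 was the 1 lower of 27, and adjusted over the list alone DSP was higher and GRHL2 lower (camera adjusted p = 0.885). Among basal keratinocyte genes KRT14, the type I keratin of the basal layer, was the 1 higher of 18, and adjusted over the list alone it was again 1 (camera adjusted p = 0.409). KRT14 rose by 0.69 ± 0.17, from 20.6 ± 3.80 to 33.4 ± 6.17 CPM (adjusted p = 0.0281). Its call was lost with limma-voom, under library totals alone, after GC correction (adjusted p = 0.0652, at a log2 fold change of 0.64) and without soft replicate 1 (0.158), soft replicate 3 (0.11), stiff replicate 1 (0.137) or stiff replicate 2 (0.320). DESeq2 gave KRT14 no adjusted p with its filter and 0.496 without it, at a log2 fold change of 0.70, and the range over alternatives was 0.0130 to 0.496. Keratinocyte differentiation genes had 0 of 33 called (list adjusted p = 0.865), with S100A9 at 6.75 and 11.5 CPM and NOTCH3 at 112 and 109. Genes of the epithelial-mesenchymal transition had 0 of 24 called (0.409), with LGALS1 at 10.3 and 14.0 CPM and CD44 at 120 and 115. Both lists had 0 called adjusted over the list alone.

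No gene passed the threshold in the remaining lists by edgeR, and none did adjusted over the list alone. Silent genes had counts per kb as high as ribosomal protein genes, as given below. A missing call, here or in the lists above, therefore does not show that vesicle RNA was unchanged. Over all lists with 0 called, 50 of 560 genes had an unadjusted p under 0.05, DESeq2 called 1 (AGRN) and limma-voom 0. Of these, the interferon response had 35 members with 23 above 0 (camera adjusted p = 0.107), with OAS2 at 27.0 and 37.1 CPM and OAS3 at 51.1 and 54.3. Hypoxia genes (29 tested, list adjusted p = 0.885) included ADM at 18.05 and 12.7 CPM and GPI at 79.7 and 79.3. Cell cycle genes (38, 0.973) included TYMS at 20.02 and 28.2 CPM and CCND1 at 69.8 and 78.0. Vesicle biogenesis and marker genes (54, 0.923) had a median of 0.01 with a mean and a test direction below 0, and included HSPA8 at 13.3 and 8.79 CPM and SMPD3 at 81.6 and 85.0. Nuclear oxidative phosphorylation genes (66, 0.923) had a median of −0.04 beside −2.93 for the mitochondrially encoded ones, with ATP5MG at 4.16 and 7.66 CPM and SDHC at 68.7 and 71.2. Nuclear-retained long RNAs (15, 0.487) included NEAT1 at 239 and 208 CPM (adjusted p = 0.279) and KCNQ1OT1 at 403 and 412. Stress response genes of the unfolded protein and integrated pathways (25, 0.798) included CRELD2 at 31.7 and 40.5 CPM and CANX at 53.7 and 55.3. Markers of other cells and materials were counted in all libraries too. Haematopoietic and erythroid markers (19, 0.885) included HBA2, an alpha-globin gene, at 11.1 and 15.9 CPM and ITGA2B at 45.1 and 45.3. Stromal and endothelial markers (15, 0.749) included KDR at 18.06 and 23.02 CPM and COL1A1 at 92.3 and 90.05. Serum and liver markers (14, 0.906), with a median of 0.02 and a mean and test direction below 0, included SERPINA1 at 27.7 and 20.2 CPM and TF at 127 and 128.

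Counts per kb of exon were as high for genes that squamous cells do not use as for genes that all cells use. Olfactory receptor genes, which are silent outside sensory neurons in most tissues, had a median of 11.9 ± 0.278 counts per kb in soft and 10.7 ± 0.435 in stiff libraries (SD, n = 3 each; 380 genes). Cytosolic ribosomal protein genes, among the most abundant messengers of growing cells, had 9.30 ± 0.323 and 10.2 ± 0.504 (72 genes). The ratio of the former to the latter was 1.28 ± 0.0544 in soft and 1.05 ± 0.0930 in stiff, with groups that did not overlap (exact permutation p = 0.1). Autosomal protein-coding genes had 16.9 ± 0.378 and 16.01 ± 0.795 (18291 genes). Mitochondrial genes stood at 3709 ± 508 and 460 ± 57.5, which is 219 ± 26.5 and 28.6 ± 2.26 times the autosomal median. Across 24992 genes, which are not independent replicates, counts followed exon length with a Spearman correlation of 0.679 to 0.694 within each library.

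**Figure D3:**
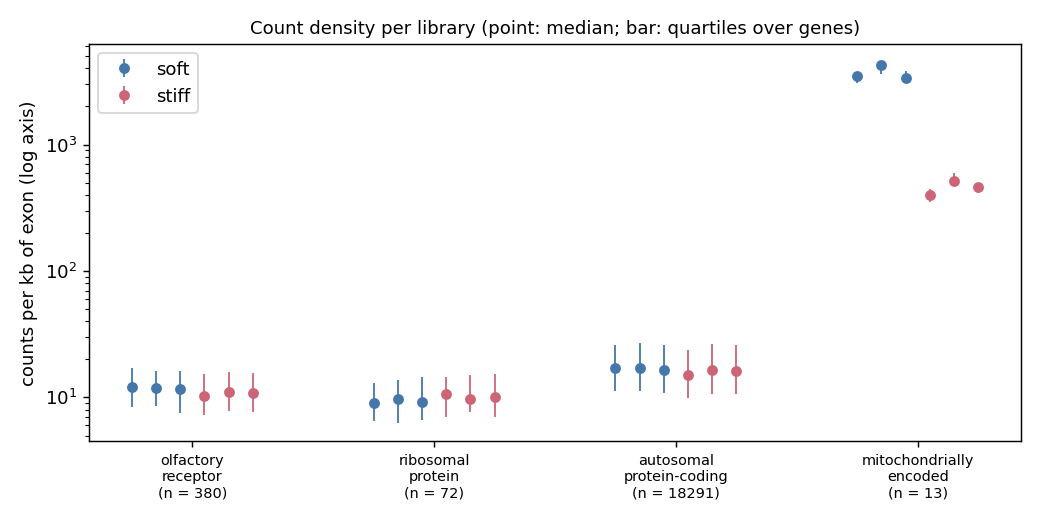
Counts per kb of exon (log axis) for 4 groups of genes in each of the 6 libraries, with points at the median over genes and bars from the lower to the upper quartile. Olfactory receptor genes (11.9 in soft, 10.7 in stiff) lie level with ribosomal protein genes (9.30 and 10.2), and mitochondrial genes lie far above both, lower in stiff (460) than in soft (3709).

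Genes higher in stiff were rich in G and C. Nuclear protein-coding genes tested had a median GC content of 49.1%, and those higher in stiff 64.3%. Across protein-coding genes the median log2 fold change went from −0.04 for 2775 genes of up to 40% GC to 0.19 for 746 genes above 65%, and that last group held 38 of the genes higher in stiff. Calls outside the mitochondrial, ribosomal and small structured RNAs were then followed through GC correction. Of those with a GC value, 25 of 80 higher genes and 25 of 28 lower genes kept the call. ANP32B, TMSB10, SLCO5A1, EEF1A1 and GRHL2 were among them, at 1.76, 1.51, 1.19, 1.08 and −0.56. The higher calls that were lost cannot be told apart from a GC bias between the libraries.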

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

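The GC correction, alone or with the replicate block, DESeq2 without its independent filtering and the class of ribosomal RNA were chosen after the data were seen, and the other alternatives were planned. Against 140 genes called, RLE factors called 142 (140 of them the same), upper-quartile factors 128 (125 the same), fits without robust estimation 133 (121), no filter 142 (136), the stricter filter 145 (139) and leaving out the mitochondrial, ribosomal and small structured RNAs 115 (113 of the 118 still tested). Larger shifts, for which the cause was not tested unless given, came from library totals alone (4194, 31 higher and 4163 lower, where the whole distribution moved by −0.27), DESeq2 (67, 47 and 20, with an adjusted p for 2157 genes), DESeq2 without independent filtering (43, 28 and 15), limma-voom (91, of which 28 lower), an adjusted p under 0.1 (223, 137 and 86), a test against a 1.5-fold change (20, 6 and 14), the GC correction (74, of which 27 higher) and the GC correction with the replicate block (84, of which 33 higher). With 1 library left out, so with fewer samples, the count was 60 to 136, with 37 to 103 higher and 23 to 46 lower. With the GC correction, the share of calls outside the mitochondrial, ribosomal and small structured RNAs that stayed past the threshold was 0.463 (50 of the 108 with a GC value), 0.312 for higher genes (25 of 80, whose median log2 fold change went from 0.48 to 0.34 with a standard error of 0.113) and 0.893 for lower genes (25 of 28, while 10 other lower genes had no GC value and were not tested). Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 140, and the highest other gave 0, and 10 splits are too few for a share under 0.05. Libraries of the same replicate number were no more alike than others, with correlations of −0.000835, 0.00349 and −0.00592. Pairs of unlike number lay between −0.0069 and 0.00753. With all values this near 0, the measure could hardly show a pairing, so whether the numbers pair the samples stays open. The replicate block gave 173 genes. Of the 24 lists, 5 were called, and 3 under library totals alone, 3 with the RNA classes left out (which removes 2 of the lists), 1 with an estimated correlation and 3 with fry in its directional test. The mixed test of fry passed 11 lists, but it also passed 63 of 240 random lists after adjustment, against 0 in the directional test. An unadjusted p under 0.05 was seen for 40.8% of the random lists in the mixed test and 8.33% in the directional one. PIEZO1 was called in no alternative. ARHGEF17, KCNQ1OT1 and TF turned to −0.27, −0.24 and −0.26 and were called under library totals alone, which is the shift of the whole distribution. The ratio of stiff to soft for the share of ribosomal protein genes turned from 0.958 to 1.149 over protein-coding counts alone, a denominator without ribosomal RNA, and those of mitochondrial and histone genes moved from 0.108 to 0.1299 and from 0.688 to 0.8266. The ratio for ribosomal RNA was 4.03, and 3.301 to 6.018 with 1 library left out, highest without soft replicate 3. The ratio of genes detected moved from 0.985 to 0.9978 at 1 count and to 0.9568 with libraries thinned to 2445498 counts. Signs changed without a call in 48 of 1184 comparisons of named genes and 26 of 502 of lists. At this depth and with 3 libraries per group, simulated 1.5-fold changes were recovered for 37.3% of genes.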

Other observations

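Of the tests below, those of olfactory receptor genes against ribosomal protein genes and of PIEZO1 against its neighbours were set out before their results were seen, and those of chromosome levels, ND6, scaling, summed ribosomal RNA counts, 45S counts outside the mature parts and ribosomal protein genes were chosen afterwards.

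Counts followed the chromosomes in every library, with a wider range in soft. After adjustment for GC content, protein-coding genes on chromosome 9 stood at 1.35 times the autosomal level, those on chromosome 20 at 1.30, on chromosome 7 at 1.19 and on chromosome 13 at 1.17, while those on chromosome 18 stood at 0.762 and on chromosome 4 at 0.672. The SD between libraries of these levels was 0.014 to 0.068 on the log2 scale for these chromosomes. Between the highest and the lowest autosome the range was 1.06 ± 0.00853 in soft and 0.955 ± 0.0255 in stiff (SD, n = 3 each; exact permutation p = 0.1), and the groups did not overlap on 6 of 22 autosomes, among them chromosome 18 (−0.45 and −0.34) and chromosome 4 (−0.61 and −0.54). MIR12136, which lies on chromosome 1 at 632615 to 632685 and was picked out after its values were seen, was lower in stiff by a log2 fold change of −2.59 (edgeR adjusted p = 4.38e-08), close to the −2.93 of the mitochondrial genes. MIR3648-1, also picked out afterwards and within the spacer ahead of 18S in the 45S unit on chromosome 21 (8208473 to 8208652), had a log2 fold change of −0.50 (adjusted p = 0.00538), which was −0.91 after GC correction (adjusted p = 5.43e-12), against 2.16 without that correction for RNA45SN2, which contains it.

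Nearly every gene had counts in every library, silent genes included. Genomic DNA carried into the libraries is a candidate explanation, since olfactory receptor genes reached at least 0.952 times the density of ribosomal protein genes in each library, where messenger RNA alone would leave them near 0. Unequal chromosome copies, usual in carcinoma lines, are consistent with the same source, as the range of the autosome medians was at least 0.939 on the log2 scale in each library against at most 0.344 in 1000 shuffles of the genes, although RNA from extra copies could also add to it. Whether any PIEZO1 count comes from RNA stays open, because its highest percentile among 261 like genes was 86.2, above the level set for pure background (75) and below that set for RNA (95). No biological explanation was tested for this pattern, which both conditions share.

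Mitochondrial genes were lower in stiff, with log2 fold changes from −3.03 for ND6 to −2.70 for ND3. Mitochondrial messenger RNA as the main source is argued against by ND6, whose messenger is by textbook knowledge far scarcer than the other 12, and whose counts per kb were at least 1.53 times their median in each soft library; coverage was not even, since the highest count per kb of the 13 was 2.94 ± 0.296 times the lowest in soft and 2.70 ± 0.00831 times in stiff, and antisense RNA over ND6 could add to its counts if reads were counted without regard to strand. A shift of the scale by the ribosomal RNA in stiff libraries is excluded as the whole cause, since the median of the 13 genes was −2.93 or lower under 3 other scalings. What stays open is whether vesicles of soft cultures held more mitochondrial DNA, or whether particles or cell debris with mitochondria differed between the cultures, and neither was tested.

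Ribosomal RNA and 7SL RNA were higher in stiff. Reads divided between gene copies do not account for it. The summed ribosomal RNA counts differed by a ratio of 4.57, or 3.72 to 6.90 with 1 library left out, and the 45S sums by 4.27. More ribosomal DNA is argued against by the 45S counts outside the mature RNAs, whose ratio of stiff to soft was 0.761 relative to all counts outside ribosomal RNA, so the excess lay in the mature parts. A larger amount of cellular RNA relative to DNA in the stiff libraries may account for it. Ribosomal protein genes had a median log2 fold change of 0.198, but this list lost its call with an estimated correlation. Under library totals alone its median was −0.07, above the −0.27 of all genes, and camera called the list higher (camera adjusted p = 3.34e-07). RPL13, its member with the most counts, stood at 0.01, but it has 6172 bp of exon and counts followed exon length, so it bears little on RNA. Not all lists of cellular RNAs rose. Medians were −0.04 for nuclear oxidative phosphorylation genes, −0.11 for nuclear-retained long RNAs and −0.29 for replication-dependent histones. EEF1A1, TPT1, PABPC1 and GAPDH rose as single genes, but they were picked from the calls, so they do not test this explanation. Processed copies also leave EEF1A1, TPT1 and GAPDH uncertain. An effect of matrix stiffness on vesicle cargo and a difference in RNA recovery or DNA carry-over between the cultures stay open, and the design does not separate them. Stiff gels also held more Matrigel, at 12 against 3 mg/mL. An effect of stiffness therefore cannot be told apart from one of the amount of gel.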
